A study of Mus musculus with 2 samples.

How the data were processed

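The data are RNA-seq libraries of LPS-treated RAW264.7 cells, 1 labelled wild type and 1 labelled RNF138 knockout, each taken from the title and genotype label of its sample. Per the labels' protocols, total RNA was extracted with Trizol, fragmented, reverse-transcribed with random hexamers and amplified by PCR, and no molecular identifiers are described. Whether the library preparation marks the strand is not given in the sources used here.

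The authors deposited a single table of 54532 genes, with an Ensembl gene identifier, symbol, GRCm38 coordinates, length and biotype for each. Raw read counts per gene in that table were made by the authors with CASAVA 1.8, HISAT2 2.0.5 and featureCounts 1.5.0-p3 on GRCm38 (mm10), per the submitters' processing notes, which do not assign a role to each tool. The strand setting of the counting, the annotation release and any filter are not given in the sources used here. The FPKM values were computed by the authors, and the values show counts divided by the table's gene length and by a fixed number per library equal to 96.6% and 96.2% of the total counts. A further pair of columns holds a signal that the authors made by scaling the counts between the libraries, and their scale ratio, 0.827, equals the ratio of the TMM scale used here to that precision. The log2 fold changes in the authors' deposited table are ratios of that signal. The p-values in the authors' deposited table, raw and adjusted by the Benjamini-Hochberg method, come from a tool and an assumed spread that are not given in the sources used here, since 1 library per group gives no spread. No column of per-sample values was left unmapped to a sample. Gene identifiers and coordinates were compared with GENCODE M21 on the same build, in which 54495 identifiers were found and 53585 of these had the same start and end.

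The raw counts were the basis of all ratios computed here. Libraries were scaled with trimmed mean of M-values (TMM) factors from edgeR 4.0.16 in R 4.3.3, which were 1.01 for the library labelled wild type and 0.995 for the library labelled knockout, and CPM are counts divided by the scaled totals. No edgeR or DESeq2 test was run, because 1 library per group gives no estimate of replicate spread. Intervals of CPM are exact Poisson intervals, and intervals of a ratio are exact Clopper-Pearson intervals conditional on the sum of the paired counts, both at 95% and both covering counting error only. At 100 counts the interval of a CPM reaches up to 21.6% from the value, and at 10 counts up to 83.9%. A library at 0 counts was set to a floor of 3 counts for a ratio, which takes the other library's count as read. The limit of the exact interval is given beside it as the bound. Genes with a mean count of at least 10 over the libraries were called measured. The size rule asked for a measured gene, a ratio of at least 2-fold in either direction and an interval excluding 1. Log2 ratios, labelled knockout over labelled wild type, had 0.5 counts added to each library before scaling.

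For each of 30 gene lists, the median log2 ratio over measured members was given with a 95% order-statistic interval, or with no interval where fewer than 6 members were measured. Its percentile was taken among 10000 random lists of the same size matched on mean count in 20 bins, which describes these libraries and not the conditions. In 25 lists enough members were measured, and 5 lists of other cell types were reported as counts. Differences between the late and early lists were compared with 10000 pairs of random lists. The lists, the size rule, the processing alternatives and the rule for named genes were chosen before the data were examined.

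Named genes were Rnf138 and Smarcc1, then Tnf, Il1b, Il6, Il12b, Nos2 and Cxcl10, then the 12 highest and 12 lowest ratios among protein-coding genes past the size rule with at least 5 CPM in the higher library, and then up to 4 members of each list with the largest difference past the rule, or the 2 most abundant where none passed. Some genes that fall under this rule are not reported here. Any other gene is said to have been chosen after its values were seen. Where a symbol belonged to several identifiers, the one with the highest mean count was used. Exon overlap of each named gene with other genes was taken from GENCODE M21, since overlapping reads cannot be assigned without a stated strand.

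Alternatives were DESeq2 1.42.0 size factors, total counts, upper-quartile factors, log2 of the deposited FPKM plus 1, no count filter, a minimum mean count of 100, protein-coding genes alone, 1.5-fold and 4-fold limits, ratios without an interval, intervals wholly beyond 2-fold, 5 counts added, means in place of medians, and random lists matched on gene length too. Removal of the trends with gene length and GC content, the latter from the longest GENCODE M21 transcript of each gene, was added after the data were seen. The procedure was tested on simulated counts for 12668 genes in these libraries with known changes. All 50 genes made 4-fold higher and all 50 made 3-fold higher in the library labelled knockout passed the size rule, as did 49 of 50 made 4-fold lower and 46 of 50 made 3-fold lower. Of 12468 unchanged genes, 45 passed it, and the intervals covered the true ratio for 95.2% of genes. The simulated counts held Poisson error only, without spread between cultures or PCR duplicates. These figures therefore give no error rate for the genes past the rule in the real libraries. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. Sequencing reads were not used here.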

Results

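RNA sequencing was used to count transcripts in RAW264.7 cells, a mouse macrophage-like tumour line. Both cultures had been exposed for 3 h to lipopolysaccharide (LPS), a component of the bacterial outer membrane that activates Toll-like receptor 4, at 100 ng/ml. The series holds 2 libraries, 1 labelled wild type and 1 labelled RNF138 knockout, so each group had 1 library and no difference reported here has a replicate check. The library labelled wild type held 15573989 counts, and 18130 genes had at least 1 count in it. The library labelled knockout held 19032311 counts, 1.22 times as many, and 19566 genes had at least 1 count. Protein-coding genes took 97.7% of the counts in each library. The 10 most abundant genes took 5.80% of the counts in the library labelled wild type and 5.06% in the library labelled knockout. Transcripts of the mitochondrial genome took 3.21% and 2.34%. No unstimulated culture was analysed here, so none of the values measures induction by LPS. Intervals are at 95%. Those of a single gene's level or ratio cover counting error only, because each group had 1 library. Reads amplified by PCR without molecular identifiers are not independent molecules, so these intervals may be too narrow even for counting error. Those of a list's median are order-statistic intervals over its member genes.

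The gene targeted in the knockout, Rnf138, encodes a RING-type ubiquitin ligase, and its level in each library checks the labels. Rnf138 transcripts were more abundant, not less abundant, in the library labelled knockout. The gene (ENSMUSG00000024317, GRCm38 chromosome 18, 21001341 to 21028223, plus strand) had 602 counts in the library labelled wild type and 4764 in the library labelled knockout. These counts correspond to 38.4 CPM (counts per 1000000 of the scaled library total, exact Poisson interval 35.4 to 41.6) and 252 CPM (245 to 259). The level was 6.55-fold higher in the library labelled knockout (exact interval 6.01 to 7.14), or 2.71 on the log2 scale. In the authors' deposited table the log2 fold change of Rnf138 was also 2.71. Counts summed over a whole gene do not show whether part of it was deleted, so a transcript with an edited exon would still be counted. Because the targeted gene goes against the label, the groups are named throughout as the library labelled wild type and the library labelled knockout, and every direction given rests on those labels.

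The series concerns late inflammatory genes and SMARCC1, a core subunit of the SWI/SNF chromatin-remodelling complexes. Transcripts of Smarcc1 (ENSMUSG00000032481, GRCm38 chromosome 9, 110117708 to 110240178) were 1.21-fold lower in the library labelled knockout (interval 1.15 to 1.26), with 3813 counts (243 CPM) in the library labelled wild type and 3822 counts (202 CPM) in the library labelled knockout. Of 25 measured genes for SWI/SNF subunits, 24 did not pass the size rule, which asks for a mean count of at least 10, a difference of at least 2-fold and an interval of the ratio that excludes 1. Their median log2 ratio, labelled knockout over labelled wild type as in all ratios below, was -0.00 (interval -0.23 to 0.14), at percentile 50.8 of 10000 random gene lists matched on expression. The subunit gene past the rule was Ss18l1, with 11 and 52 counts, 3.91-fold higher in the library labelled knockout (2.02 to 8.31). These values concern transcripts, and the amount of SMARCC1 protein was not analysed here.

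**Figure D1:**
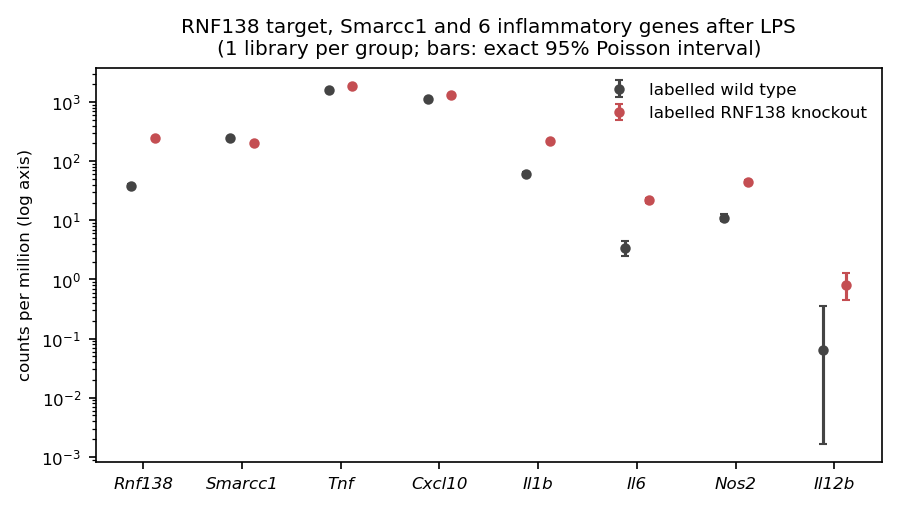
CPM (log axis) of Rnf138, Smarcc1 and 6 inflammatory genes in the library labelled wild type and the library labelled RNF138 knockout, 1 library each, with exact 95% Poisson intervals as bars. Rnf138 stands at 38.4 and 252, Tnf and Cxcl10 differ by 1.18-fold and 1.17-fold, and Il1b, Il6 and Nos2 lie higher in the library labelled knockout.

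The question whether late LPS-induced genes differ between the cultures was addressed with 6 inflammatory genes and with lists of early and late LPS targets. Tnf, the tumour necrosis factor gene and an immediate target of LPS signalling, had 25256 counts in the library labelled wild type and 35910 in the library labelled knockout, a ratio of 1.18 (1.16 to 1.20). Il6, Nos2 and Il1b stood further apart. Il6, which encodes the cytokine interleukin-6, was 6.49-fold higher in the library labelled knockout (4.87 to 8.81, 53 and 416 counts). Nos2, the gene of inducible nitric oxide synthase, was 4.05-fold higher (3.44 to 4.79, 175 and 857 counts), and Il1b, which encodes interleukin-1 beta, was 3.53-fold higher (3.29 to 3.79, 967 and 4123 counts). Cxcl10, a chemokine gene induced through interferon signalling, had a ratio of 1.17 (1.15 to 1.20, 17672 and 25079 counts). Il12b, which encodes a shared subunit of interleukin-12 and interleukin-23, had 1 and 15 counts and a ratio of 12.4 (1.91 to 522), below the minimum mean count. On GRCm38 these genes lie at chromosome 17, 35199381 to 35202007 (Tnf), chromosome 5, 30013114 to 30019981 (Il6), chromosome 11, 78920787 to 78960254 (Nos2), chromosome 2, 129364570 to 129371139 (Il1b), chromosome 5, 92346638 to 92348889 (Cxcl10) and chromosome 11, 44400063 to 44414033 (Il12b).

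Late LPS targets were higher in the library labelled knockout as a list, and early targets were not. Of 13 measured late genes, 8 were past the size rule and higher in the library labelled knockout, none was lower and 5 were not past the rule. Their median log2 ratio was 1.36 (interval 0.27 to 2.51), above all 10000 random lists. Saa3, an acute-phase serum amyloid gene, was 15.6-fold higher in the library labelled knockout (11.6 to 21.5, 46 and 869 counts). Lcn2, the gene of the iron-sequestering protein lipocalin-2, was 5.85-fold higher (3.39 to 10.8, 15 and 106 counts), and Il27, a cytokine subunit gene, was 5.03-fold higher (4.47 to 5.67, 329 and 1999 counts). The other 7 of the 20 late genes, Il12b and Il10 among them, were below the minimum count. Of 20 measured early genes, 3 were higher, 1 was lower and 16 were not past the rule, with a median log2 ratio of 0.06 (-0.08 to 0.23) at percentile 74.8. The early genes that were higher were Cxcl2, a neutrophil-attracting chemokine gene, at 3.55-fold (3.45 to 3.65, 5749 and 24654 counts), Ptgs2, the gene of cyclooxygenase-2, at 3.52-fold (3.27 to 3.80), and the transcription factor gene Egr1 at 2.02-fold (1.89 to 2.15). The orphan nuclear receptor gene Nr4a1 went the other way and was 4.32-fold lower in the library labelled knockout (3.35 to 5.63, 279 and 78 counts). The late median exceeded the early median by 1.30 on the log2 scale, above all 10000 pairs of random lists of these sizes, whose central 95% ran from -0.31 to 0.37 and whose highest value was 0.79. Apobr lies on the opposite strand over 10.1% of the Il27 exons, and reads of the overlap cannot be assigned when the counting strand is not stated.

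Genes of the type I interferon response were the list furthest from 0. Of 23 measured members, 20 were past the size rule and higher in the library labelled knockout, none was lower, and all 23 had a ratio above 1. Their median log2 ratio was 2.13 (1.32 to 2.89), a median of 4.37-fold, above all 10000 random lists. Cxcl10, with a ratio of 1.17, was among the 3 members not past the rule. It held 17672 of the 25222 counts of the list in the library labelled wild type. Summed over all 26 members, the list stood at 1611 CPM in that library and 2663 CPM in the library labelled knockout. The 4 members named next had the largest ratios. Oas2, which makes the second messenger that activates RNase L, was 26.0-fold higher (14.7 to 50.8, 12 and 377 counts). Zbp1, a sensor of Z-form nucleic acid, was 14.3-fold higher (4.64 to 71.8) on 3 and 52 counts. Mx2, of the antiviral dynamin-like GTPase family but with the biotype polymorphic pseudogene in the authors' deposited table, was 9.12-fold higher (6.42 to 13.4, 34 and 375 counts). Gbp2, which encodes a guanylate-binding protein active against intracellular microbes, was 9.02-fold higher (5.70 to 15.1, 20 and 218 counts). Cytokine genes were also higher as a list in the library labelled knockout, with 11 of 20 measured genes higher, 2 lower and 7 not past the rule, and a median of 1.08 (0.56 to 1.54) above all random lists. They included Csf3, the gene of granulocyte colony-stimulating factor, at 4.47-fold (4.21 to 4.76, 1223 and 6612 counts), and Tnfsf15 at 8.27-fold (2.01 to 73.0) on 2 and 20 counts. Tnfsf9 and Vegfa, named after their values were seen as the pair that was lower, were 2.27-fold (2.13 to 2.41) and 2.76-fold (1.93 to 3.99) lower. Chemokine genes had 9 of 14 measured members higher, none lower and 5 not past the rule, with a median of 1.34 (0.23 to 1.83) above all random lists. Among them were Cx3cl1, whose product attracts CX3CR1-bearing monocytes, at 7.61-fold (3.04 to 24.5, 5 and 46 counts), Ccl22, a ligand of the receptor CCR4, at 4.11-fold (3.53 to 4.81, 203 and 1009 counts), and Cxcl3 at 3.66-fold (1.58 to 9.86, 7 and 31 counts). The lists are not independent, since 8 members of the late list are also in the cytokine list and 4 members of the early list are chemokines. On log2 of the authors' FPKM, a unit scaled by gene length and library size, plus 1, a scale that shrinks ratios of weakly expressed genes, the medians were 1.11 for interferon response genes, 0.70 for cytokines and 0.73 for chemokines.

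**Figure D2:**
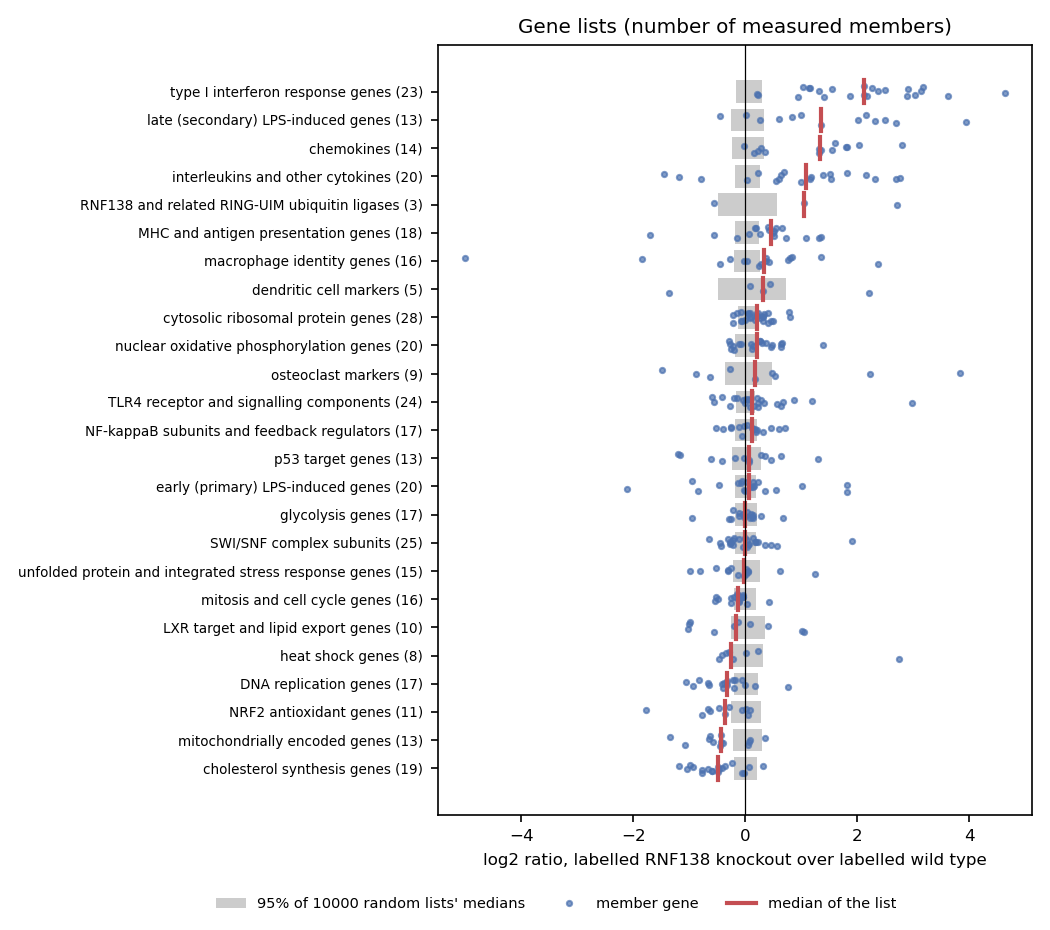
Log2 ratio of the library labelled knockout over the library labelled wild type for each measured member (blue points) of 25 gene lists, with the list median (red) and the central 95% of the medians of 10000 random lists matched on expression (grey). Interferon response genes (median 2.13), late LPS targets (1.36) and chemokines (1.34) lie furthest to the right, and cholesterol synthesis genes (-0.49) furthest to the left.

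None of 17 measured genes for NF-kappaB subunits and feedback regulators passed the size rule, and their median log2 ratio was 0.12 (-0.10 to 0.21) at percentile 89.1. Nfkb1, the gene of the p105 and p50 subunit, had a ratio of 1.53 (1.49 to 1.56, 9864 and 18202 counts), and the inhibitor gene Nfkbia had a ratio of 1.02 (0.994 to 1.05). Of 24 genes for the TLR4 receptor and its signalling components, 2 were higher in the library labelled knockout and 22 were not past the rule, with a median of 0.12 (-0.04 to 0.33) at percentile 92.5. Irak3, the gene of an inhibitory kinase-like protein of this pathway, was 7.97-fold higher (6.42 to 10.0, 91 and 877 counts), and Ikbke, a kinase gene of the interferon-inducing branch, was 2.28-fold higher (2.17 to 2.40). Tmbim4 lies over 5.22% of the Irak3 exons on the opposite strand. Of the ubiquitin ligases related to RNF138, Rnf114 was 2.06-fold higher (1.87 to 2.28, 570 and 1420 counts). The 3 measured members of that list, Rnf138 included, had a median of 1.04 at percentile 99.8, and the median over all 5 members without a count minimum was 0.38.

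Across the transcriptome, 12668 genes had a mean count of at least 10, of which 828 (6.54%) were past the size rule and higher in the library labelled knockout and 458 (3.62%) were lower. Among the 10785 protein-coding genes, 605 were higher and 346 were lower. The standard deviation of the log2 ratio over genes was 0.76 for these 12668 genes and 0.54 for the 9411 genes with a mean count of at least 100. Among protein-coding genes past the size rule with at least 5 CPM in the higher library, the highest ratio was that of Cd84, a receptor of the SLAM family (GRCm38 chromosome 1, 171839697 to 171890718), with 3 counts in the library labelled wild type and 345 in the library labelled knockout, a ratio of 95.1 (32.3 to 464). The 42 other measured genes within 1 Mb of Cd84 had a median log2 ratio of 0.84 (0.64 to 0.95), and 40 of them were above 0. Fbxo47, an F-box protein gene, had 14 and 998 counts, 59.0-fold higher in the library labelled knockout (35.0 to 108). The zinc-finger genes Zfp985 and Zfp979, neighbours on chromosome 4, had 2 and 117 counts (ratio 48.4, interval 13.1 to 404) and 11 and 249 counts (18.7-fold higher, 10.3 to 38.0). They belong to a family of similar sequences, so reads could be split between its members. The 12 highest ratios in this group also held Oas2, Saa3 and Gbp2, the interferon-induced gene Xaf1 at 9.49-fold (6.60 to 14.1), and Cebpe, a transcription factor gene of granulocyte and macrophage maturation, at 8.54-fold (5.50 to 13.9). Fsd1l and Fam19a2 were 8.98-fold (5.67 to 15.0) and 9.02-fold (4.72 to 19.3) higher. Ldlrad4 was 20.2-fold higher (11.7 to 38.4), but 52.1% of its exon length overlaps Fam210a on the opposite strand, so that value is uncertain.

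At the low end, several genes were close to absent from the library labelled knockout. Psd4, which encodes an exchange factor for ARF6 (GRCm38 chromosome 2, 24367580 to 24414954), had 408 counts in the library labelled wild type and 2 in the library labelled knockout, a ratio of 247 in favour of the former (67.8 to 2043), and Pkd1l1 had 161 and 1, a ratio of 195 (34.4 to 7734). Kif13a, a kinesin gene with 203 and 0 counts, was at least 65.9-fold lower in the library labelled knockout by its exact interval. It was 81.8-fold lower when its 0 was set to a floor of 3 counts. B630019K06Rik, with 86 and 0 counts, was at least 27.6-fold lower by its exact interval and 34.7-fold lower against that floor. Lin28b, which encodes an inhibitor of let-7 microRNA maturation, had 108 and 3 counts (ratio 43.5, interval 14.5 to 214), and Rbbp9 had 87 and 3 counts (ratio 35.1, interval 11.6 to 173). Cd36, the scavenger receptor and fatty acid transporter gene (GRCm38 chromosome 5, 17781690 to 17888801), had 1083 and 40 counts, 32.7-fold lower in the library labelled knockout (23.9 to 46.1). The laminin gene Lama4, the kinesin gene Kif26a and the matrix protein gene Sparc were 27.2-fold (10.3 to 102), 24.8-fold (11.1 to 68.8) and 20.7-fold (9.75 to 52.6) lower. Adgre5 was also 20.7-fold lower (13.1 to 34.9), with 23.8% of its exon length overlapping Ddx39 on the opposite strand. When the whole interval had to lie beyond 2-fold, 353 genes were higher and 185 lower.

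**Figure D3:**
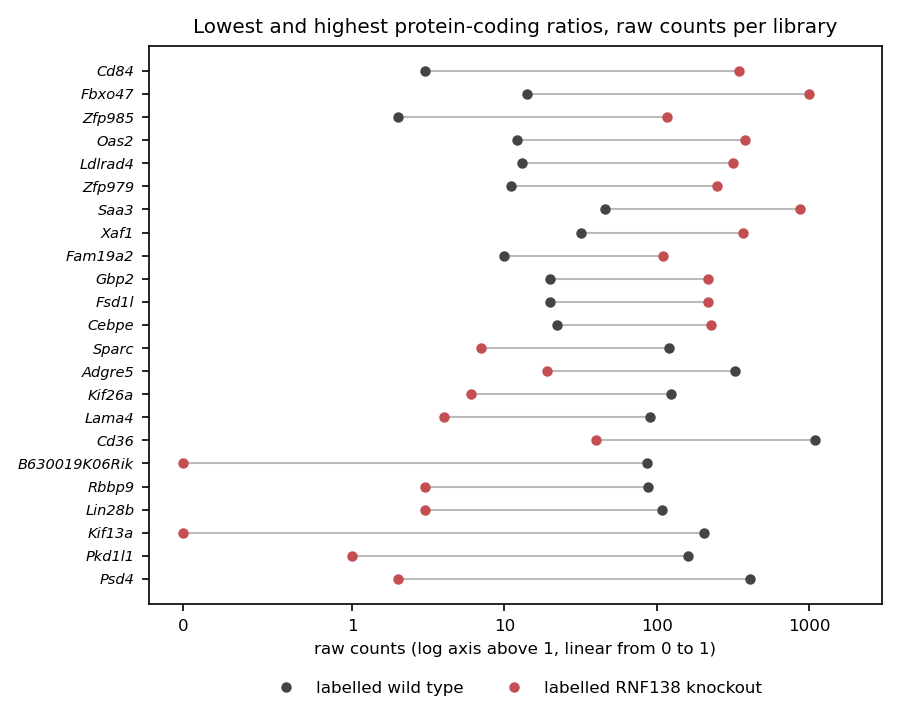
Raw counts (log axis above 1, linear from 0 to 1) in the library labelled wild type (black) and the library labelled knockout (red) for protein-coding genes with the 12 highest ratios and 11 of the 12 lowest among those passing the size rule with at least 5 CPM in the higher library. Cd84 goes from 3 to 345 counts, and Psd4 from 408 to 2.

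Most genes that define macrophages were present in both libraries, with a few members far apart. Of 19 such genes 3 were at or near 0, chosen for naming after their counts were seen: Mertk and Mrc1 had 0 and 1 counts each, and Cd163 had 0 and 0. Of 16 measured macrophage identity genes, 2 were higher in the library labelled knockout, 2 were lower and 12 were not past the rule, and the median log2 ratio was 0.33 (-0.27 to 0.81) at percentile 99.3, against a mean of 0.02. Msr1, a scavenger receptor gene, was 5.33-fold higher (3.23 to 9.31, 18 and 116 counts) and Lyz2, the lysozyme gene of myeloid cells, was 2.55-fold higher (2.46 to 2.64, 4351 and 13391 counts). Adgre1, which encodes the F4/80 antigen, was 3.58-fold lower (3.02 to 4.26, 542 and 183 counts), beside Cd36. Of 9 osteoclast markers, 2 were higher, 1 was lower and 6 were not past the rule (median 0.17, interval -0.88 to 2.23, percentile 74.4). Mmp9 had 2 and 43 counts, a ratio of 17.8 (4.63 to 152), the fusion gene Ocstamp was 4.71-fold higher (3.78 to 5.94), and Nfatc1, the master transcription factor gene of osteoclasts, was 2.82-fold lower (2.66 to 2.98, 4009 and 1719 counts). Of 5 measured dendritic cell markers, Itgax was 4.67-fold higher (3.26 to 6.85), Siglech was 2.58-fold lower (2.20 to 3.03) and 3 were not past the rule (median 0.32, percentile 81.3). Genes of antigen presentation had 3 of 18 members higher, 1 lower and 14 not past the rule, with a median of 0.46 (0.17 to 0.67) at percentile 99.96. Nlrc5, the activator of class I genes, Cd40 and the peptide transporter gene Tap1 were 2.58-fold (2.16 to 3.09), 2.49-fold (2.28 to 2.72) and 2.13-fold (1.76 to 2.58) higher, and the costimulatory gene Cd86 was 3.25-fold lower (210 and 78 counts) in the library labelled knockout.

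Markers of other cell types were near background in both libraries. All markers of neutrophils (12 genes) summed to 14 counts in the library labelled wild type and 21 in the library labelled knockout, those of B lymphocytes (9 genes) to 6 and 24, those of fibroblasts (9 genes) to 10 and 19, and those of epithelia (8 genes) to 3 and 2, with no member at a mean count of 10. Within these lists Prtn3 had 3 and 11 counts, Cxcr2 4 and 4, Cd79a 2 and 4, Pdgfrb 2 and 10, Cldn4 3 and 1, and Cdh1 0 and 1. Blk, a B-lymphocyte kinase gene, had 0 and 15 counts, at least 2.97-fold higher in the library labelled knockout by its exact interval and 4.14-fold higher against the floor of 3 counts. Thy1 had 0 and 9 counts, at least 1.63-fold higher by its exact interval and 2.48-fold higher against the floor. Markers of T lymphocytes (9 genes) summed to 62 and 99 counts, with 2 members measured, of which Lck was 2.07-fold higher (1.24 to 3.56, 22 and 55 counts). The floor of 3 counts is 0.192 CPM in the library labelled wild type and 0.158 CPM in the library labelled knockout. It is a set value, and the exact Poisson interval of a count of 0 reaches 0.236 CPM and 0.195 CPM, respectively.

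Proliferation genes were close between the libraries, with replication genes slightly lower in the library labelled knockout. None of 16 mitosis genes passed the size rule (median -0.13, interval -0.25 to -0.04, percentile 12.6), and the proliferation marker Mki67 and the topoisomerase gene Top2a had ratios of 0.929 (0.907 to 0.952) and 0.920 (0.895 to 0.945). Of 17 DNA replication genes, 1 was lower and 16 were not past the rule, with a median of -0.33 (-0.64 to -0.18) at percentile 0.07. The replication licensing factor gene Cdt1 was 2.08-fold lower in the library labelled knockout (1.95 to 2.22, 2560 and 1487 counts). Of 13 p53 targets, Gadd45a was 2.47-fold higher (1.82 to 3.39) while Trp53inp1 and Pmaip1 were 2.34-fold (1.24 to 4.58) and 2.25-fold (1.96 to 2.57) lower, and 10 were not past the rule (median 0.07, mean -0.03, percentile 65.8). A transcript on the opposite strand covers 19.1% of the Gadd45a exons. Of 15 unfolded protein and integrated stress response genes, Trib3 was 2.37-fold higher (1.86 to 3.05) and 14 were not past the rule (median -0.02, percentile 39.2). Of 8 heat shock genes, Hspa1b was 6.82-fold higher (4.63 to 10.4, 29 and 239 counts) and 7 were not past the rule. The median of that list was -0.26 at percentile 3.62 and its mean was 0.16, and Hspa1b shares nearly all of its sequence with Hspa1a, so its count is uncertain. Of 11 NRF2 antioxidant genes, the quinone reductase gene Nqo1 was 3.53-fold lower (1.79 to 7.46, 35 and 12 counts) and 10 were not past the rule, with a median of -0.37 (-0.78 to 0.04) at percentile 0.21.

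Genes of cholesterol synthesis were lower in the library labelled knockout as a list. Of 19 measured members, 2 were lower by the size rule and 17 were not past it, with a median log2 ratio of -0.49 (-0.77 to -0.23), below all 10000 random lists. Insig1, the sterol-responsive brake on this pathway, was 2.26-fold lower (2.10 to 2.44, 1908 and 1019 counts), and Stard4, a cholesterol transport gene, was 2.06-fold lower (1.86 to 2.29, 977 and 572 counts). Of 10 LXR targets and lipid export genes, 2 were higher, 2 were lower and 6 were not past the rule (median -0.17, interval -1.01 to 1.01, percentile 8.84). The cholesterol exporter gene Abca1 and the receptor gene Nr1h3 were 2.08-fold (1.37 to 3.22) and 2.03-fold (1.32 to 3.19) higher, and Mylip, which encodes a ligase for the LDL receptor, and Apoe were 2.03-fold (1.51 to 2.74) and 2.01-fold (1.79 to 2.27) lower. No glycolysis gene of 17 passed the rule, with a median of 0.01 and a mean of -0.02 at percentile 48.6. The log2 ratio of Pkm was 0.13 and that of Aldoa was -0.12.

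Mitochondrially encoded genes were lower in the library labelled knockout than random lists, and nuclear genes of oxidative phosphorylation were not. Of 13 mitochondrially encoded genes, 2 were lower in the library labelled knockout and 11 were not past the rule, with a median of -0.43 (-0.64 to 0.07) at percentile 0.02. These 2 genes, mt-Atp6 at 2.55-fold lower (2.35 to 2.78) and mt-Atp8 at 2.14-fold lower (1.04 to 4.60), overlap on the same strand, and their counts are uncertain. Nuclear genes of oxidative phosphorylation had 1 of 20 members higher and 19 not past the rule, with a median of 0.20 (-0.10 to 0.47) at percentile 98.4. The member past the rule was Ndufb3, a complex I subunit gene, 2.61-fold higher (2.34 to 2.92, 426 and 1343 counts). None of 28 cytosolic ribosomal protein genes passed the rule, with a median of 0.20 (0.06 to 0.32) at percentile 98.9, and Rpl4 and Rpl8 had ratios of 1.06 (1.05 to 1.08) and 1.32 (1.29 to 1.35). Short genes had higher ratios in these libraries, with a median log2 ratio of 0.22 in the tenth of genes with the shortest length and -0.03 in the tenth with the longest. With random lists matched on gene length as well the percentiles of the oxidative phosphorylation and ribosomal protein lists were 92.6 and 89.3. With length and GC trends removed their medians were 0.13 and 0.01.

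Of the 25 lists with a median, 9 lay above the central 95% of random lists, 4 lay below it and 12 lay within it. The 9 are not separate shifts, since some share members and the list of ligases related to RNF138 includes Rnf138 itself. The oxidative phosphorylation and ribosomal protein lists came within the central 95% when random lists were matched on gene length too. The authors' deposited table gives p-values for 18843 genes from the same pair of libraries. At an adjusted p below 0.05, the authors' deposited table holds 272 genes higher and 145 genes lower in the library labelled knockout, and 388 of those 417 genes in the authors' deposited table also pass the size rule used here. With 1 library per group, the p-values of the authors' deposited table rest on an assumed spread between replicates and compare these libraries, not the conditions.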

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

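Removal of the trends with gene length and GC content was chosen only after the results had been seen, and the other alternatives were planned. The counts of genes past the size rule, 828 higher and 458 lower in the library labelled knockout, depended on how the rule was set. They were 359 and 187 on log2 of the deposited FPKM plus 1, 327 and 161 with a mean count of at least 100, 1634 and 1021 at 1.5-fold, 218 and 128 at 4-fold, and 353 and 185 when the interval had to lie wholly beyond 2-fold. A pseudocount of 1 FPKM shrinks ratios of weakly expressed genes, and the other settings take in fewer or more genes by construction. Under DESeq2 size factors, total counts and upper-quartile factors the counts ran from 804 to 812 higher and from 466 to 467 lower. The share of genes past the rule that were higher ran from 61.5% to 67.0% over all of these settings, against 64.4% in the main setting. The interferon response median, 2.13, was 1.11 on log2 of the deposited FPKM plus 1, and the ribosomal protein median, 0.20, was 0.012 with length and GC trends removed. The other 274 combinations of a main result and an alternative stayed within 1.5 times the count or within the spread of the list. Among them the median changed sign 11 times in 5 lists, each within the central 95% of random lists: with means in place of medians in the heat shock (-0.26 to 0.16), p53 target, glycolysis and SWI/SNF lists, with length and GC trends removed in the early (0.06 to -0.04) and glycolysis lists, without a count filter in the SWI/SNF list, and for glycolysis also under the other 3 scalings and on log2 of the deposited FPKM plus 1. The late minus early difference, 1.30, ran from 1.11 with the length and GC trends removed to 1.62 with a mean count of at least 100. Of 93 named genes, all stayed within their counting interval under the other 3 scalings, and 50 moved beyond it on log2 of the deposited FPKM plus 1. With lists matched on gene length too, the percentiles of the oxidative phosphorylation and ribosomal protein lists moved to 92.6 and 89.3.

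No paired analysis was possible because each group had 1 library. Depth limits the genes with few counts: Il12b, with 1 and 15 counts, had a ratio interval from 1.91 to 522, and no spread between cultures was measured for any gene.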

Other observations

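The tests on copies of Rnf138, exchanged labels, scaling, gene length and GC content, LPS timing, counting error and the region around Cd84 were chosen only after the result was seen, as were the gene families and single genes described here, while those on the region around Rnf138 and on chromosome segments around all near-absent genes were set before, and the bound for length and GC content was revised after an earlier bound had left the late list open. Directions rest on labels that Rnf138 goes against. Some members of further interferon-inducible families were higher in the library labelled knockout, while others were not past the size rule or were lower. Of 5 measured guanylate-binding protein genes, 4 passed the size rule and were higher (median log2 ratio 2.47), among them Gbp5, which promotes inflammasome assembly, at 6.16-fold (5.14 to 7.43, 135 and 1005 counts). The 3 measured immunity-related GTPase genes were all higher, with Irgm1 at 3.16-fold (2.80 to 3.57). Of 7 Schlafen genes 3 were higher, with Slfn5 at 14.9-fold (5.57 to 56.1) on 4 and 72 counts, and of 11 Parp genes 3 were higher, with Parp14 at 4.28-fold (3.99 to 4.59). Of the 2 measured Ifi200 family genes, Ifi207 was 3.66-fold higher (3.21 to 4.19) and Ifi202b was 3.11-fold lower (1.85 to 5.42). Some transcription factor genes of this response were higher, with Irf7 at 7.62-fold (5.46 to 10.9), Irf9 at 3.48-fold (3.08 to 3.95) and Irf1 at 3.20-fold (2.73 to 3.77). Irf3, Irf5 and Irf8 were not past the rule. Ifnb1, the interferon-beta gene, had a ratio of 1.63 (1.22 to 2.20, 71 and 140 counts). Members of these families share sequence, so their counts are uncertain.

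Of 11 measured genes often used as microglia markers, 5 were lower in the library labelled knockout, none was higher and 6 were not past the rule. The lower ones included the purinergic receptor gene P2ry12 at 4.82-fold lower (3.86 to 6.07, 399 and 100 counts) and Tmem119 at 3.45-fold lower (2.94 to 4.06), while Cx3cr1, Csf1r and Trem2 were not past the rule, with log2 ratios of 0.25, 0.04 and -0.02. Axl, a receptor for the clearance of apoptotic cells, was 11.9-fold lower (7.08 to 21.3, 157 and 16 counts), and Cd109 was 6.21-fold lower (5.66 to 6.82). Receptor genes went both ways. Of 3 measured Fc gamma receptor genes, 1 was higher and none was lower by the size rule. It was the inhibitory receptor gene Fcgr2b, which lies within 1 Mb of Cd84, at 4.96-fold higher (4.51 to 5.45). Of 8 measured Toll-like receptor genes, 2 were higher, among them Tlr1 at 5.48-fold (4.04 to 7.59), and 1 was lower, Tlr13 at 2.46-fold (2.14 to 2.83). The median log2 ratio of these 8 genes was -0.30. Gapdh had 500 and 651 counts beside 46196 and 61203 for Pkm.

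Rnf138 was 6.55-fold higher in the library labelled knockout. Reads of the annotated copy, Rnf138rt1, stay open as a contribution, since its 0% of the Rnf138 count in the library labelled knockout would also arise if its reads were assigned to Rnf138. A gain of the surrounding region stays open too, because only 3 other genes within 1 Mb were measured, all on the same side of Rnf138, and their log2 ratios of -0.44 to -0.15 (median -0.38) give no interval, which the bound set before needs. An exchange of the labels stays open, because 38.4 CPM of Rnf138 in the library labelled wild type could come from an edited allele that is still transcribed or from an unedited line, and no other gene in the table marks the genotype. A knockout allele whose altered transcript accumulates, or a construct that carries Rnf138 sequence, also stays open and was not tested.

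Interferon response and late LPS genes were higher in the library labelled knockout. A scaling factor shared by all genes is argued against, since it cancels in the difference between the median of a list and that of all other measured genes. That difference was 2.11 (1.30 to 2.87) for the interferon list and 1.34 (0.25 to 2.48) for the late list. Each lay beyond all 10000 random lists, which restates the percentiles given earlier and is not a separate test. Length and GC trends are argued against as the whole cause for the interferon list. With the trends removed its median was 2.14 (1.21 to 2.81), above all 10000 random lists. The late median was 1.07 (0.15 to 2.39, from 1.36) with the trends removed, also above all 10000 random lists, so part of the late value went with the trends. The bound that the late list meets was set after an earlier bound had left it open, so no verdict is drawn for that list. A longer or stronger LPS exposure of a single culture cannot be told apart from the genotype, since either may give late genes 1.30 above early genes when each group is a single culture. A genotype effect remains a hypothesis whose direction depends on the labels.

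In all, 18 genes had at least 50 counts in either library and at most 3 in the other, 9 in each direction, such as Psd4 and Kif13a on the side of the library labelled wild type and Cd84 and Clu (0 and 62 counts) on the other. Poisson counting error alone is argued against, since 100 simulated pairs of libraries with equal expression gave 0 such genes in every draw. The simulation held no PCR duplicates and no spread between cultures, so it does not address these. Gain or loss of segments that span most neighbours within 1 Mb is argued against as a shared cause for these genes as a set. The 263 other measured genes within 1 Mb had a median log2 ratio, signed by the direction of the gene they neighbour, of 0.070 (0.021 to 0.181). It was 0.020 over 221 genes without those near Cd84. Neighbours that were unmeasured or themselves near absent were left out, so the pooled median cannot show a loss confined to a gene or a few neighbours, or a shift at a single locus. Cd84 stands apart, since 40 of its 42 neighbours were higher, with a median of 0.84 (0.64 to 0.95), which is far below the 6.35 of Cd84 itself but leaves a regional contribution open. A candidate explanation is that the cultures descend from different single cells with different stably silenced genes, which this design confounds with genotype and which was not tested, and part of the 828 and 458 genes past the size rule may then reflect clone and not RNF138.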
